A study of Drosophila melanogaster with 6 samples.

How the data were processed

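Messenger RNA was profiled in mushroom body output neurons sorted from Drosophila melanogaster brains, in 3 libraries with a bantam sponge and 3 with a scramble sponge. Per the labels' protocols and the series design, poly(A) RNA was purified on beads, reverse transcribed and amplified over 25 PCR cycles by a modified SMART-seq2 protocol, and made into libraries with Nextera XT. Per the labels, 2 biological replicates were sequenced on a NextSeq with paired 75-base reads and 1 on a HiSeq with paired 150-base reads. Which replicate went on which instrument was not given in the sources used here, so platform could not be a term in any test. Reads were aligned with STAR to dm6, and Picard, HTSeq and edgeR are named in the submitters' processing notes without versions. The order and settings of these steps were not given in the sources used here.

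The file used is the authors' deposited table of 1 comparison, with 17117 rows named by gene symbol and 3 columns of values. The log2 fold changes in it (bantam sponge over scramble sponge) and the mean log2 CPM over all libraries were computed by the authors, per the file headers and name, as an edgeR exact test. Its p-value column holds the authors' unadjusted exact-test p-values, per the file headers. Values per library were not analysed here, so no SD, no library left out and no replicate block could be computed. In 5 rows the gene symbol had been turned into a calendar date; these rows stayed in the totals and are not named. Coordinates and gene types come from the Ensembl release 115 annotation on the same assembly as dm6, in which 16959 rows found a gene, 3695 of them through an older symbol.

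The plan had been to use the authors' adjusted p. The table holds none, so Benjamini-Hochberg and Holm adjustments were computed here from the deposited p-values over all 17117 rows. The threshold was an adjusted p of 0.05, two-sided.

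Depth was recovered from the table. Genes with 1 read in 1 library fall on 6 distinct mean log2 CPM values, from which the 6 effective library sizes and a common dispersion of 4.50 (biological coefficient of variation 2.12) were solved, taking the default prior counts of the authors' tool (2 for the mean, 0.125 for the fold). Of 147 low genes that were not used for the solution, 141 (95.9%) fell within 1e-05 of a value predicted for 2 or 3 reads, and 0% did at shifted values. The sizes include any normalization factor, and which replicate had which size is not known. For genes with a mean log2 CPM of at least 0, a gene was taken to have no read in a genotype when the absolute log2 fold change exceeded the mean log2 CPM by more than 9.3; no gene lay between 8.34 and 9.66. The fold of such a gene depends on the prior count and is not printed. Its mean CPM in the other genotype was inferred from the fold and the prior count instead.

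For 5520 genes with reads in both genotypes and a mean log2 CPM of at least 3, the dispersion used by the exact test was recovered from the deposited fold and p, and with it a 95% interval of the log2 fold change for 3 libraries per genotype. The absolute log2 fold change also had to be at least 0.02 and to exceed the mean log2 CPM by less than 5. Genes with the largest folds for their expression, such as gammaCOP, were thus left out and have no interval. These intervals restate the authors' deposited p-values and hold no information on single libraries. On simulated data for dispersions of 1.2, 2.5 and 5, 94.7%, 94.6% and 95.1% of the intervals from 4000 simulated genes held the true value. These intervals were built with the simulated dispersion, so this checks the formula only. It does not show how often intervals of the real genes hold the true fold.

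Before the data were examined, 34 gene lists were fixed, 29 by symbol and 5 by a pattern of symbols. They cover described bantam targets, genes thought to have been followed up by the study, small RNA proteins, transmitter and cell type markers, channels, receptors, and housekeeping complexes. The pattern for mitochondrially encoded genes, a symbol prefix, matched 0 rows, because the table writes these genes without it (COX1, COX2, COX3 and CYTB, for example); COX1, COX2 and COX3 were counted with the oxidative phosphorylation subunits. Lists of at least 3 genes with reads were tested for a shift with limma cameraPR (preset correlation 0.01, Benjamini-Hochberg over 30 lists) on a signed z made from the deposited p and the sign of the fold. Genes are not replicates, so these tests describe the 6 libraries. On simulated lists of 15 genes cameraPR called 14 of 20 shifted by 0.8 in z and 0 of 20 unshifted lists. The median fold of each list was also placed among 10000 random lists drawn from the 200 genes nearest in mean expression.

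The named genes follow a rule fixed before the data were examined. It takes the 12 genes with the smallest p in each direction, said not to pass where none passes, all members of the bantam target and follow-up lists, and the 2 most expressed members of each other list. All other genes in the text were chosen after their values were seen, among them elav, Gad1, per, repo, ninaE, Arr2, Sr-CI and CR43334 and the list members with an unadjusted p under 0.05. A planned comparison of genes with and without bantam seed sites was not run because no genome sequence was used here. Alternatives covered the adjusted p threshold, a minimum fold, filters on mean expression, Holm adjustment, and the statistic, the preset correlation and the gene set of the list tests.

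Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Random draws used a fixed seed of 11.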

Results

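The series measured messenger RNA in 3 types of mushroom body output neuron of the adult Drosophila melanogaster brain, the γ5β′2a, β′2mp and β′2mp_bilateral neurons, which carry signals out of the mushroom body, a centre for learning and for sleep control. The cells were labelled with membrane-bound GFP and isolated by fluorescence-activated sorting from mated females aged 3 to 4 days, with brains dissected between ZT12 and ZT13.5 (hours after lights-on). In 1 genotype the neurons expressed a sponge for bantam, a transcript with binding sites meant to sequester this microRNA; in the other they expressed a scrambled sponge. Each genotype had 3 libraries described as biological replicates. The comparison asks which messenger RNAs change in these neurons when bantam is sequestered. All gene values below come from the authors' deposited table of 17117 genes, which gives a log2 fold change (bantam sponge over scramble sponge), a mean log2 CPM (read counts scaled to library size) over both genotypes and an exact-test p-value, but no value per library. Most folds are therefore given with the interval that the deposited p implies rather than with an SD, and some without either.

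Depth differed widely between libraries. The effective library sizes recovered from the low values of the authors' deposited table were 119.1, 43.8 and 8.18 megareads for bantam sponge and 98.0, 43.6 and 5.31 megareads for scramble sponge, a range of 22.4 times. Reads were found for 9286 genes (54.3%), and the other 7831 had no read in any library. A genotype listed with no read for a gene can still hold up to 3 reads' worth of it, 0.0175 CPM in the bantam sponge libraries and 0.0204 CPM in the scramble sponge libraries. These limits cover counting error only, since reads amplified over 25 PCR cycles are not independent molecules.

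Pan-neuronal transcripts and that of the vesicular glutamate transporter were abundant in the sorted cells, with folds near 0 and wide intervals. In the authors' deposited table VGlut, the transporter gene (2L, 2400295 to 2410662, dm6), had a mean log2 CPM of 10.70 and a log2 fold change of −0.20 (95% interval −3.07 to 2.68, exact-test p = 0.887). The other glutamatergic gene, Got2, an aspartate aminotransferase, was at 6.45 with a fold of −3.10 (−9.28 to 3.08, exact-test p = 0.267) in the authors' deposited table. The vesicle protein gene nSyb stood at 10.35 with a fold of 0.30 (−2.54 to 3.14), and the neuronal RNA-binding protein gene elav at 8.64 with −0.54 (−3.75 to 2.66), in the authors' deposited table. Of 10 pan-neuronal genes 6 had folds above 0 and 4 below, and none reached an unadjusted p under 0.05. Transcripts of other transmitter systems were present at lower levels: ChAT, for acetylcholine synthesis, at 8.50, Gad1, for GABA synthesis, at 6.62, and Ddc and SerT, of monoamine neurons, at 8.48 and 8.25 log2 CPM in the authors' deposited table. None of these 4 genes reached an unadjusted p under 0.05. The other monoaminergic markers were scarcer than Ddc and SerT. Trh had no read in any library, and DAT was at 0.12 log2 CPM, with Vmat and Hdc lower still.

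The bantam locus itself could not be used to check the sponge. The hairpin mir-ban (3L, 642208 to 642288, dm6) lies within the noncoding gene lncRNA:CR43334 (628435 to 643900). In the authors' deposited table the row named ban had no read in any library, and CR43334 had a log2 fold change of 1.60 at a mean log2 CPM of 2.66 (exact-test p = 0.756). A sponge sequesters the mature microRNA, which poly(A) libraries do not measure.

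No gene differed between bantam sponge and scramble sponge at an adjusted p under 0.05 in the authors' edgeR exact test with Benjamini-Hochberg adjustment over all 17117 genes, where the smallest adjusted p was 0.467. At an unadjusted p under 0.05 there were 388 genes, 98 higher and 290 lower in bantam sponge, against 464.3 expected by chance if p-values of the genes with reads were uniform. Of these 388 genes 247 (63.7%) had no read in 1 genotype, 188 in bantam sponge and 59 in scramble sponge. The genes named next are those with the smallest p in each direction, and none of them passed the adjusted threshold.

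Among the 12 genes with the smallest p and a higher value in bantam sponge, the uncharacterised gene CG8245 (2R, 5668383 to 5669986) came first, with no read in scramble sponge and an inferred 214 CPM in bantam sponge (exact-test p = 5.5e-05, authors' deposited table). Cdc27, a subunit of the anaphase-promoting complex (3L, 7245481 to 7249340), was read in both genotypes, with a log2 fold change of 9.03 (95% interval 4.52 to 13.54, exact-test p = 0.00108 in the authors' deposited table). PVRAP had a fold of 10.09 (4.68 to 15.49, exact-test p = 0.00218) in the authors' deposited table. CCHa2-R, the receptor of the peptide CCHamide-2 (2R, 6050949 to 6068680), had no read in scramble sponge and an inferred 135 CPM in bantam sponge (exact-test p = 0.00156, authors' deposited table). CG13575, Idgf4, Ets97D, CG5377 and CG5815 likewise had no read in scramble sponge, with inferred levels of 85.7 to 224 CPM in bantam sponge. The translation initiation factor gene eIF2B-epsilon, CG31637 and CG6094 made up the remainder, with exact-test p-values of 0.00175, 0.00209 and 0.00476 in the authors' deposited table. They were classed as read in both genotypes, but their log2 fold changes of 13.97, 12.10 and 11.75 leave few reads in scramble sponge.

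Among the 12 with the smallest p and a lower value in bantam sponge, gammaCOP, a subunit of the COPI vesicle coat (3R, 31572143 to 31575707), had the smallest p of all genes, 4.1e-05 by the exact test in the authors' deposited table, with a mean log2 CPM of 6.72. It was classed as read in both genotypes, but its log2 fold change of −14.90 leaves few reads in bantam sponge. The autophagy protease gene Atg4b and the Golgi stacking protein gene Grasp65 had no read in bantam sponge and an inferred 150 and 136 CPM in scramble sponge (exact-test p = 0.000456 and 0.000646, authors' deposited table). PPO1, a prophenoloxidase of insect blood cells (2R, 17887220 to 17889973), had no read in bantam sponge and an inferred 1336 CPM in scramble sponge (exact-test p = 0.000634, authors' deposited table). The antifungal peptide gene Drs also had no read in bantam sponge, against an inferred 209 CPM in scramble sponge, as did CG31849, Ppox, CG2111 and lectin-24Db at 141, 145, 164 and 208 CPM. CG6227, Cbs and CG4951 were classed as read in both genotypes, with exact-test p-values of 0.00130, 0.00193 and 0.00217 in the authors' deposited table. Their log2 fold changes of −11.92, −14.14 and −14.16 leave few reads in bantam sponge. Of the genes given with values in this section, Ets97D, eIF2B-epsilon, CG6094, Atg4b, Ppox, CG4951, VGlut, elav, Got2, Ddc, CR43334, brat, Pxn, Yp1, repo, per, AGO1, Dcr-2 and p53 overlap in some exonic sequence with a gene on the opposite strand. Overlaps with an annotated gene or element on the same strand were found for ChAT (with VAChT), Idgf4, elav, Pxn, CR43334 (with mir-ban and others), sav and pasha. SMART-seq2 with Nextera XT does not mark strand, so reads from the shared parts, whose extent was not measured, cannot be told apart by strand, nor can those of same-strand overlaps.

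**Figure D1:**
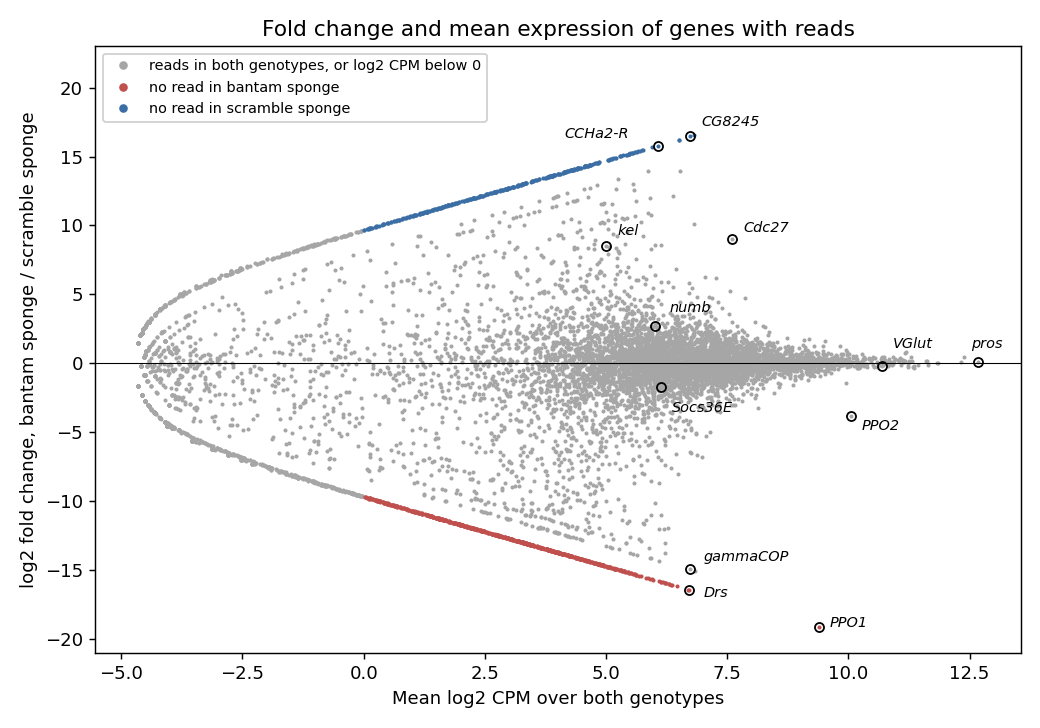
Each point is a gene with reads, placed by its mean log2 CPM over both genotypes (x axis) and its log2 fold change, bantam sponge over scramble sponge (y axis), with genes that had no read in bantam sponge in red and those with none in scramble sponge in blue, classed from a log2 CPM of 0 up. The red band holds 617 genes and the blue band 326, and circles mark 12 named genes, with VGlut and pros close to 0.

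Genes described as direct bantam targets in other tissues were not higher as a group. Of 9 such genes, all with reads, 2 had folds above 0 and 7 below, and none reached an unadjusted p under 0.05 or an adjusted p under 0.05 over the list alone. Those above 0 were numb, an inhibitor of Notch signalling (log2 fold change 2.69, 95% interval −3.22 to 8.60), and Mad, a BMP pathway transcription factor (1.49, −4.85 to 7.82), in the authors' deposited table. The enabled gene ena had a fold of −2.13 (−9.15 to 4.90), Socs36E −1.70 (−7.03 to 3.64), cic −0.49 (−4.70 to 3.71) and brat −0.17 (−5.46 to 5.13) in the authors' deposited table. The proapoptotic gene hid and the clock gene Clk were scarce, at mean log2 CPM of 1.06 and −1.08, and trbl had no read in bantam sponge and an inferred 6.23 CPM in scramble sponge. The list's shift had an adjusted p of 0.767 (limma cameraPR). These intervals span many-fold changes in either direction, so a release of the size usual for a microRNA was not detectable here.

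Both genes thought to have been followed up by the study were higher in bantam sponge at an unadjusted p under 0.05. Apart from CCHa2-R, this was kel, which encodes the actin-binding ubiquitin ligase adaptor Kelch (2L, 18129884 to 18138083), with a log2 fold change of 8.53 (95% interval 0.39 to 16.66) and an exact-test p of 0.0427 in the authors' deposited table. Adjusted over the list alone both passed 0.05, which is not counted as independent evidence because the pair may have been chosen on these libraries. Over all genes their adjusted p was 1. Within the list of peptide receptors CCHa2-R had an adjusted p of 0.0609 over the list alone.

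Markers of 3 kinds of cell other than the sorted neurons shifted towards lower values in bantam sponge: photoreceptor, hemocyte and fat body (limma cameraPR, adjusted p = 0.0129, 0.0129 and 0.0261 over 30 lists). Of the 12 photoreceptor markers with reads 11 had folds below 0, of the 8 hemocyte markers 7, and of the 7 fat body markers 5. The rhodopsin gene ninaE, Arr2, the hemocyte scavenger receptor gene Sr-CI and the yolk protein gene Yp1 had no read in bantam sponge and inferred levels of 32.5, 42.0, 20.9 and 32.8 CPM in scramble sponge. Another rhodopsin gene, Rh4, went the other way, with no read in scramble sponge and an inferred 15.6 CPM in bantam sponge. Arr2, Yp1 and a further yolk protein gene, Yp3, had an unadjusted p under 0.05 (exact-test p = 0.0445, 0.0335 and 0.0271, authors' deposited table). The most abundant member of each list was closer to equal: norpA at −0.38 (95% interval −4.89 to 4.13), Pxn at 0.72 (−2.47 to 3.91) and FASN1 at 1.25 (−2.85 to 5.35), in the authors' deposited table. No member passed an adjusted p of 0.05, over all genes or over the list alone. All 3 calls ended at a preset correlation of 0.05 (adjusted p = 0.0656 each), that of fat body markers on ranks (0.169), and those of photoreceptor and hemocyte markers among genes at or above the median expression of genes with reads (0.654 and 0.276), where fat body markers were too few to test. An estimated correlation needs library values, which were not analysed here.

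Markers of other outside cells passed no shift test. Of 10 glial genes 7 had folds above 0 and 3 below (adjusted p = 0.767), with the astrocyte and cortex enzyme gene Gs2 at 1.23 and the glial fate gene repo at −6.70 (95% interval −13.50 to 0.10) in the authors' deposited table. The glial member with the smallest p was e (ebony), a β-alanyl amine synthase gene, with no read in scramble sponge and an inferred 78.1 CPM in bantam sponge (exact-test p = 0.0367, authors' deposited table). The tracheal markers had no read in any library, and of 7 muscle genes 2 were above and 5 below 0 (adjusted p = 0.883). Kenyon cells, the intrinsic neurons of the mushroom body, were represented by 9 genes, 2 above and 7 below 0 (adjusted p = 0.767). Of 8 monoaminergic markers 7 were below 0 (adjusted p = 0.210), and the 3 GABAergic markers gave an adjusted p of 0.767, although their median fold of 1.88 lay at the 97.6 percentile of lists matched on expression.

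**Figure D2:**
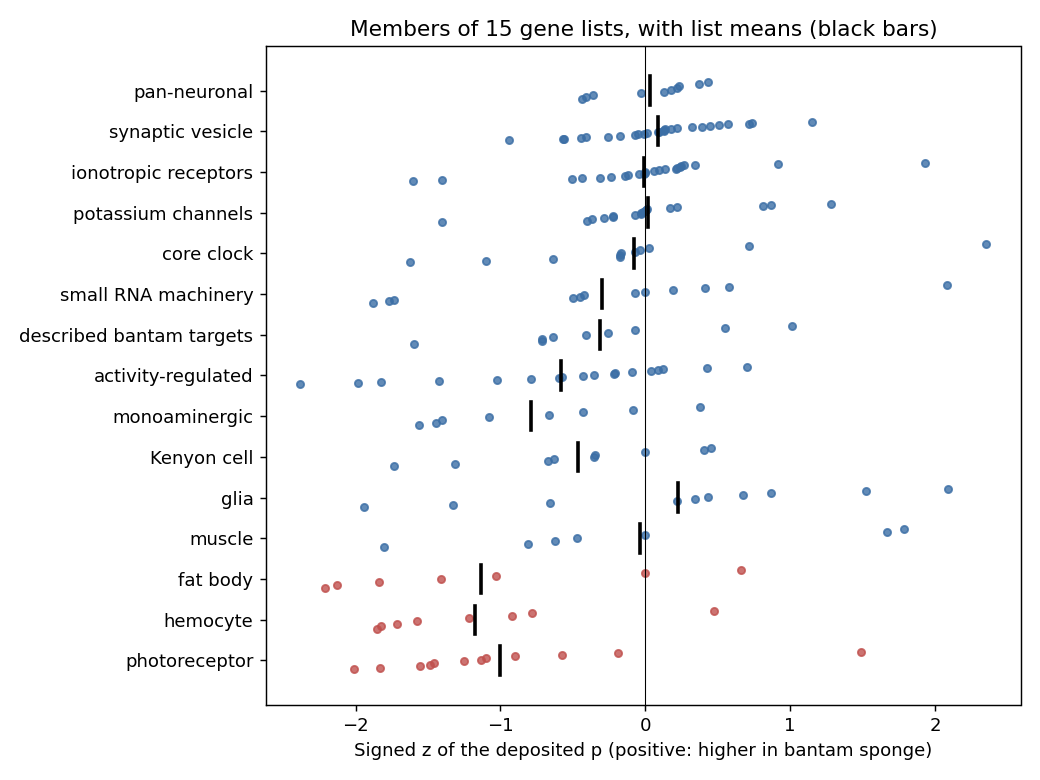
Each dot is a gene with reads, placed on the x axis by its signed z (the deposited p as a normal deviate with the sign of the fold, positive when higher in bantam sponge), for 15 of the gene lists, with list means as black bars. The fat body and hemocyte lists, in red with the photoreceptor list, have means of −1.14 and −1.18, and the pan-neuronal list has a mean of 0.03.

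Lists of neuronal function passed no shift test. Adjusted p-values were 0.767 for potassium channels, ionotropic receptors, metabotropic receptors, peptide receptors, neuropeptides and synaptic vesicle genes, and 0.883 for sodium and calcium channels and for genes with described sleep phenotypes (limma cameraPR). Within these lists the unadjusted p was under 0.05 for AstC, the gene of the peptide allatostatin C, for Nplp3, for the receptor genes GABA-B-R3, 5-HT7 and Pdfr, all lower in bantam sponge, and for CCHa2-R. In the authors' deposited table AstC and GABA-B-R3 had no read in bantam sponge, with an inferred 74.3 and 52.1 CPM in scramble sponge. Core clock genes divided 3 above and 8 below 0 (adjusted p = 0.938); the Clock partner gene cyc had a log2 fold change of 8.61 (95% interval 1.93 to 15.30, exact-test p = 0.0186) and per −0.49 (−7.34 to 6.37) in the authors' deposited table. Activity-regulated genes were mostly below 0, 13 of 18, without passing the adjusted threshold (adjusted p = 0.210), and the most abundant members, CG14186 and Arc1, had folds of −0.32 (−3.51 to 2.88) and −0.33 (−3.58 to 2.92) in the authors' deposited table. The activity-regulated genes CrebA, with no read in bantam sponge and an inferred 53.8 CPM in scramble sponge, and CG13055 had the smallest p-values of that list, 0.0173 and 0.0474 by the exact test in the authors' deposited table.

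The proteins that make and use small RNAs gave 5 folds above and 7 below 0 (adjusted p = 0.767). AGO1 and gw, of the microRNA effector complex, had folds of −0.67 (95% interval −4.04 to 2.69) and −0.12 (−3.62 to 3.38), and Dcr-2, of the small interfering RNA pathway, had 9.53 (0.78 to 18.27, exact-test p = 0.0374) in the authors' deposited table. The microRNA-processing genes Dcr-1 and pasha and the export receptor gene Ranbp21 were at lower values in bantam sponge without passing 0.05 (exact-test p = 0.0832, 0.0602 and 0.0766), and pasha had no read there, in the authors' deposited table. Hippo pathway and growth genes (11 above, 17 below 0), actin and Cullin regulators (12 above, 10 below) and heat shock genes (9 above, 12 below) had an adjusted p of 0.767, and apoptosis genes (5 above, 5 below) of 0.883. Within these lists the unadjusted p was under 0.05 for kel and for the lower genes sav, Thor and p53, of which Thor and p53 had no read in bantam sponge and an inferred 67.6 and 11.8 CPM in scramble sponge (exact-test p = 0.0368, 0.0218 and 0.0479, authors' deposited table). Of the 23 immune genes 8 had reads, and Drs passed an adjusted p of 0.05 over the list alone (0.0247) while the list's shift did not (0.767). Cytosolic ribosomal proteins, oxidative phosphorylation subunits and proteasome subunits each had an adjusted p of 0.767 and mitochondrial ribosomal proteins of 0.978, and RpS5b was the 1 member under an unadjusted p of 0.05, higher in bantam sponge (exact-test p = 0.0438, authors' deposited table). The shift test compares a list with all genes with reads, whose mean signed z was −0.112. In 10 lists, none of them called, its direction differed from the sign of the list's median fold, and in 7 of these also from the sign of the list's mean z, among them the core clock, muscle, ribosomal protein and oxidative phosphorylation lists. The glutamatergic, cholinergic and study lists held fewer than 3 genes with reads and were not tested for a shift.

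The share of genes with a small p depended on expression. The shares below are set against uniform p-values and do not measure the power to find a change. At a mean log2 CPM of 8 or more, 1 of 914 genes (PPO1) had an unadjusted p under 0.05, against 45.7 expected, between 5 and 8 there were 178 of 3774 (4.72%, 188.7 expected), between 3 and 5 there were 182 of 1577 (11.5%, 78.9 expected), and between 0 and 3 there were 27 of 987 (2.74%, 49.4 expected). Across genes at 10 or more the robust SD of the log2 fold change was 0.301, whereas the dispersion implied by the authors' deposited p-values would give 1.37. The expected SD was above the observed one in every range from 5 up, 1.93 times at 5 to 6 and 2.53 times at 8 to 9. The intervals above are therefore wider than the scatter of the folds themselves, most of all for abundant genes.

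**Figure D3:**
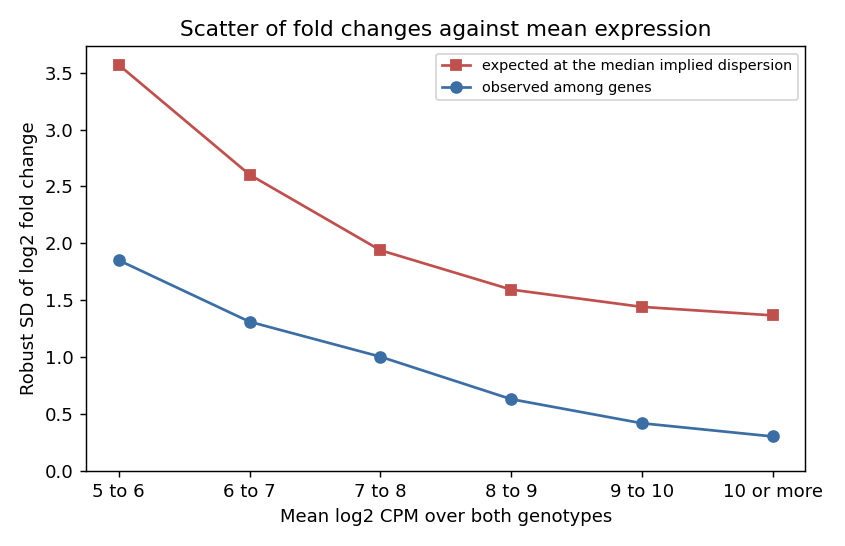
Robust SD of the log2 fold change among genes with a recovered interval (blue) and the value expected at the median dispersion implied by the deposited p-values (red), by mean log2 CPM over both genotypes. Genes with the largest folds for their expression are left out. The observed value goes from 1.85 at a log2 CPM of 5 to 6 down to 0.301 at 10 or more, and the expected value from 3.57 to 1.37.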

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

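The filters at the median expression of genes with reads, the restriction to genes read in both genotypes, the minimum fold applied to unadjusted counts and the list tests over all rows were chosen after seeing the data. The count of 0 changed genes (authors' edgeR exact test, Benjamini-Hochberg; 388 at an unadjusted p under 0.05) was 0 as well at adjusted p thresholds of 0.01 and 0.1, with an absolute log2 fold change of at least 1, with Holm adjustment and under each expression filter, where the smallest adjusted p ranged from 0.127 to 0.710. None of the 93 genes named by rule passed with adjustment over genes at or above the median expression of all rows, or with Holm adjustment. The 388 genes at an unadjusted p under 0.05 (98 higher, 290 lower) became 173 (60 and 113) at or above the median expression of genes with reads, and 141 (39 and 102) among genes read in both genotypes, since fewer genes enter. Some of these 141, such as gammaCOP, had few reads in 1 genotype. The 3 shifted lists became 0 at a preset correlation of 0.05, where photoreceptor, fat body and hemocyte markers each had an adjusted p of 0.0656. On ranks fat body markers had 0.169. Restricted to genes at or above the median expression of genes with reads, 1 list passed, the immune genes (0.0103, with 3 genes left, among them Drs with no read in bantam sponge), while photoreceptor and hemocyte markers had 0.654 and 0.276 with 3 and 4 genes left and fat body markers were too few to test. With all rows and unread genes at 0, 5 lists passed, monoaminergic (0.0262) and activity-regulated (0.0164) genes in addition. The cause of these list changes was not tested beyond the loss of genes. Of 177 list results under alternatives, 14 changed direction, all among lists without a call. No paired analysis was possible because the table holds no values per library, and for the same reason leaving out replicates, DESeq2, other normalizations, an estimated correlation and other splits of the 6 libraries were not run. The bantam seed site alternatives were not run without a genome sequence. At a mean log2 CPM of 0 to 3, 48.0% of genes had no read in 1 genotype, although the totals of both genotypes allow no more than 0.0175 or 0.0204 CPM there. Counting error at the summed depth alone does not account for these missing reads. Uneven library sizes and amplified reads that are not independent molecules were not tested, so limited sampling is not excluded.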

Other observations

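Apart from the relation with 3′ UTR length given mean expression, the tests in this part, that with the length of the rest of the transcript included, were chosen after the results were seen, as were most of the genes named here. The transcription factor gene pros was the most abundant transcript of the sorted neurons, with 6577 CPM and a log2 fold change of 0.06 (95% interval −2.73 to 2.86) in the authors' deposited table. The neuropeptide gene Dh44 ranked 17 with 2397 CPM and a fold of −0.27 (−3.09 to 2.55), in the same table. PPO2, a further prophenoloxidase, had the largest absolute fold among genes read in both genotypes at a log2 CPM of 8 or more, −3.81 (−8.50 to 0.89, exact-test p = 0.0988 in the authors' deposited table), next to PPO1 with no read in bantam sponge. Of the other COPI coat subunits, beta'COP had a fold of −5.26 (exact-test p = 0.0635) in the authors' deposited table, and alphaCOP, betaCOP, deltaCOP, epsilonCOP and zetaCOP lay between −1.03 and 0.46, unlike gammaCOP. Some exonic sequence of pros and epsilonCOP, and of tna below, overlaps a gene on the opposite strand.

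More genes were lower than higher in bantam sponge, 290 of 388 at an unadjusted p under 0.05 (74.7%, Wilson 95% interval 70.2 to 78.8 across genes, which are not independent). Shallower sequencing of the bantam sponge libraries would need a smaller total, and their total effective size was 1.16 times that of the scramble sponge libraries. Loss of low-abundance transcripts in bantam sponge libraries would give a larger share of lower genes at low expression, and the share was 83.5% at a log2 CPM of 3 to 5 and 64.6% at 5 to 8 (Fisher's exact test across genes, p = 4.1e-05), so this may contribute. Over all genes with reads, the median log2 fold change was −2.20 at 0 to 3, −0.85 at 3 to 5 and 0.03 at 5 to 8. The share of genes with no read in 1 genotype fell from 48.0% to 23.3% and 2.68% over these ranges. Within each range the balance of missing reads between genotypes was similar. Genes with no read in bantam sponge and in scramble sponge numbered 304 and 170 at 0 to 3, 247 and 120 at 3 to 5, and 65 and 36 at 5 to 8. A reduction of many messenger RNAs by the sponge itself was not tested and stays open.

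The photoreceptor, hemocyte and fat body markers were lower together. They were picked here from 30 lists for their shift and have no member in another list. Of the 27 with reads 23 had folds below 0 (85.2%), 9 had no read in bantam sponge and 1 had none in scramble sponge. The latter was the rhodopsin gene Rh4, at an inferred 15.6 CPM in bantam sponge. The photoreceptor markers Arr1, Rh3, Rh5 and ninaA had no read in any library. Dropout that depends on expression alone, with genes lost independently, rarely gave 3 lists as low, even when any 3 could be picked. In 3.25% of 10000 redraws of all 30 lists from genes of matched expression, at least 3 lay at or below the 2.31 percentile. That was the highest place among the photoreceptor, hemocyte and fat body lists. Of the 30 lists, 5 lay in the lowest 2.5% of matched lists: these 3, activity-regulated genes and ribosomal proteins. In the highest 2.5% lay 1, the GABAergic markers. On each side 0.75 would be expected if genes varied independently. Members of a list may vary together, so these counts and the redraws do not exclude dropout shared by such members. RNA of photoreceptors, hemocytes and fat body in the scramble sponge libraries is a candidate explanation. The abundant genes were divided on it and cannot decide it. The most abundant members, norpA, Pxn and FASN1, at 6.63, 9.19 and 7.36 log2 CPM, had folds of −0.38, 0.72 and 1.25 in the authors' deposited table, with wide intervals. Whether these transcripts came from the marked cell types is not known, so their folds do not weigh against outside RNA. Unlike Pxn, the hemocyte markers Hml and NimC1 were at 2.19 and 1.48 log2 CPM, and He and eater had no read. The hemocyte marker Col4a1, at 6.98 log2 CPM, had a fold of −6.80 (exact-test p = 0.0637). Outside the lists, the prophenoloxidase gene PPO2, at 10.06 log2 CPM, had −3.81. PPO1 had no read in bantam sponge and an inferred 1336 CPM in scramble sponge. Sorting for GFP was meant to remove outside cells. PPO2 and the glial marker Gs2 were nevertheless read in both genotypes, at means of 1066 and 906 CPM. With no values per library, RNA of outside cells cannot be told apart from a change in the neurons themselves.

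Almost no abundant gene had a small p, which bears on what this comparison could find. Gene dispersions shrunk close to a common trend may contribute: at a log2 CPM of 10 or more the 95th percentile of the implied dispersion was 1.08 times the 5th. The spread of single-gene estimates without shrinkage was not measured. A narrow spread also cannot show why the shared level lay above the scatter of the folds. The expected robust SD of the fold was 4.54 times the observed one. Replicate effects shared by both genotypes, such as the change of sequencing platform, could add to this excess. How much of the excess comes from such effects cannot be told apart from shrinkage without a replicate block, which needs values per library. Abundant genes with moderate folds, such as crp (2.96, 95% interval −0.51 to 6.44), Ace (2.69, −1.23 to 6.61) and tna (−2.50, −6.06 to 1.07) in the authors' deposited table, would be worth a test on the counts.

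A hypothesis was that sequestering a microRNA may raise genes with long 3′ UTRs, which hold more binding sites. Over 4574 genes at or above the median expression, Spearman's rho between 3′ UTR length and signed z, given mean expression, was 0.0321 (permutation p = 0.0301, across genes, which are not independent replicates). Length of the rest of the transcript may account for this, since with it held constant rho was −0.00146 (permutation p = 0.920). The hypothesis was left without evidence for or against it.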
